A study of Mus musculus with 12 samples.

How the data were processed

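RNA from mouse samples, named by their labels as iNKT17, ROR- or gamma-delta 17 cells, was hybridised to 12 Affymetrix whole-transcript arrays, 1 array per sample. Per the labels' protocols, total RNA was extracted with an RNeasy kit and prepared as biotinylated cRNA. The protocol names frozen tissue as the source, while the labels name cells, so how the cells were obtained was not checked here. The labels place the arrays in 5 groups: BALB/c ROR- cells (3 arrays), BALB/c iNKT17 cells (3), B6 ROR- cells (2), B6 iNKT17 cells (2) and B6 gamma-delta 17 cells (2). They name the strain and the cell type and number the replicates, but they do not say whether replicates came from separate animals, so p-values here measure only the spread between these samples, which may be technical. They also do not give the organ or the antigen receptor of the ROR- cells.

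The authors deposited a single table of processed values on a log2 scale, with 41345 probe sets per array. Per the submitters' processing notes the R package oligo was used; its version and the summarisation, background and normalization methods are not given in the sources used here. The log base is not stated either, and log2 was taken as the scale because it is the one oligo writes and the values span that of a summarised array of this kind. The quartiles of the 12 deposited columns were nearly equal and genes had not been centred. The per-array median of all probe sets lay between 4.10 and 4.30. The deposited values were used as they stand, with no further normalization in the main results.

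Probe sets were named from the platform annotation supplied with the table, which can be old. Of the 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none given here; names were never taken from a probe set with several symbols. Gene IDs were looked up in a RefSeq gene table of the mouse assembly GRCm38.p6, where 23328 matched and 0 symbols changed; that table was used only for names and gene neighbourhood. The named probe sets covered 22180 genes, 1082 of them with more than 1 probe set, for which the brightest by mean over the 12 arrays was kept. A gene was tested when at least 2 arrays lay above the 30th percentile of the named probe-set values, a log2 level of 3.45, which left 16667 genes and set aside 5513. That percentile, called the dim level, is no measured background, but where a group mean lies below it the size of a fold change is uncertain. Some genes of the lists, among them Trdc, Trac and Tcf7, are not analysed here.

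A group-means model was fitted to the log2 values of all 12 arrays with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, so that every comparison shared one estimate of the spread (7 residual and 4.50 prior degrees of freedom). The 9 comparisons were iNKT17 minus ROR- as the mean of both strains, in BALB/c and in B6; the difference between strains of that difference, called the interaction; BALB/c minus B6 in iNKT17, in ROR- and as their mean; and, in B6, iNKT17 minus gamma-delta 17 and gamma-delta 17 minus ROR-. Fold changes are limma estimates with standard errors (SE), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The number of arrays per group, 2 or 3, limits the precision of every value.

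The groups, the model, the filter, the alternatives, 26 gene lists and the rule for naming genes were fixed before the data were examined. The rule named, for the comparisons iNKT17 minus ROR- (mean of both strains), BALB/c minus B6 in iNKT17, BALB/c minus B6 in ROR- and iNKT17 minus gamma-delta 17, the 10 largest rises and 10 largest falls among genes past the threshold with at least a 2-fold change and no overlap between arrays of the groups, leaving out predicted or clone-named genes. It named 5 each way in the other comparisons, up to 4 members of each list past the threshold, and a fixed set of anchor genes whatever their values. The lists cover the type 17, type 1 and cytotoxic, and type 2 programs, the cell cycle, pro-apoptotic and anti-apoptotic genes, the T cell receptor (TCR) signal response, egress with residency and homing, interferon-stimulated genes, glycolysis, oxidative phosphorylation, lipid and cholesterol metabolism, cytokine and chemokine ligands, the Klra and Klrb families of the natural killer (NK) gene complex, major histocompatibility complex (MHC) class I and II, gamma-delta and alpha-beta T cell genes, immediate-early and heat-shock genes, ribosomal proteins, and markers of B cells, macrophages with monocytes and dendritic cells, neutrophils, erythroid cells, immature thymocytes, epithelial with stromal cells, and conventional NK with CD8 cells. For each list, members past the threshold were counted among all genes and with p adjusted over the list alone, and the list was set against all other genes with camera in limma, at a preset correlation of 0.01, adjusted over the 26 lists. Camera was repeated with the correlation estimated from the data.

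Alternatives were quantile normalization, centring each array on its median, no dim filter or a stricter one at the 50th percentile, the mean of a gene's probe sets, eBayes with trend and robust settings, array weights, a 2-fold minimum, fits on the compared groups only, the replicate number as a block, and leaving out each array in turn. The alternatives added after the data were seen were the mean of the cell cycle list as a covariate and the omission of the 2 BALB/c arrays with the highest heat-shock levels; iNKT17 and gamma-delta 17 cells were also each set against a B6 ROR- array of their own. The fitting steps were tested on simulated data for 16667 genes, 200 of them changed. Noise was drawn independently for each gene and array, with the spread estimated for that gene. It held no structure shared by many genes on an array, so recovery and false calls can be worse on the real arrays. For iNKT17 minus ROR- 96% of 2-fold and 100% of 4-fold changes were recovered, with 6 false calls; for BALB/c minus B6 in iNKT17 88% and 99%, with 9; and for iNKT17 minus gamma-delta 17 74% and 98%, with 9. The 12121 expressed probe sets with several symbols or none were tested apart from the genes, and only their counts are given.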

Results

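Invariant natural killer T (iNKT) cells are alpha-beta T cells with a semi-invariant receptor for lipids shown by CD1d, and their iNKT17 subset makes interleukin 17. The series profiled iNKT17 cells and ROR- cells of the BALB/c and B6 mouse strains, with interleukin 17-type gamma-delta T cells of B6 mice beside them, and its stated subject is how iNKT cells of these strains differ in transcription. Arrays of the same group correlated with a mean r between 0.978 and 0.988 across probe sets. The leading principal component held 43.3% of the variance and parted ROR- arrays from the iNKT17 and gamma-delta 17 arrays, and the next component held 22.4%.

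**Figure D1:**
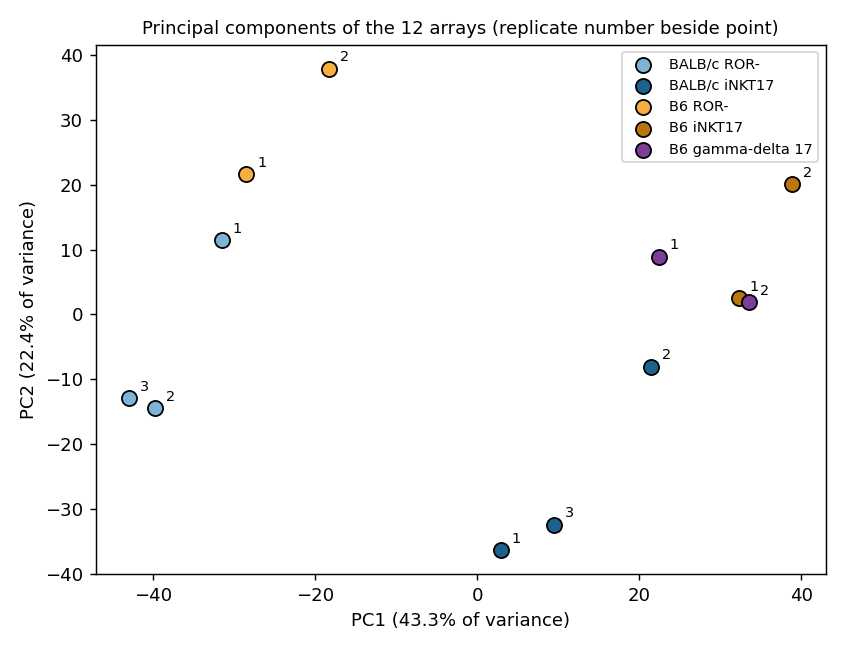
Principal component scores of the 12 arrays, with PC1 (43.3% of the variance) against PC2 (22.4%); each point is 1 array, coloured by group, with its replicate number beside it. The 5 ROR- arrays lie at negative PC1 scores and the 7 iNKT17 and gamma-delta 17 arrays at positive ones.

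The first comparison asked what sets iNKT17 cells apart from ROR- cells of the same strain. Il23r, the interleukin 23 receptor, was higher in iNKT17 cells by 6.06 ± 0.61 log2 units (SE) as the mean of both strains. It stood at 10.14 ± 0.21 (SD, n = 3) in BALB/c iNKT17 cells against 4.47 ± 2.20 in BALB/c ROR- cells, and at 9.76 ± 0.33 (n = 2) against 3.30 ± 0.52 in B6. The cytokine Il22 rose by 5.30 ± 0.69 and the interleukin 1 receptor Il1r1 by 4.99 ± 0.32. The Il22 means of both ROR- groups (3.03 in BALB/c and 2.26 in B6) and the Il23r mean of B6 ROR- cells lie below the dim level of 3.45, so the sizes of these rises are uncertain. In the other direction Klrd1, which encodes the NK receptor chain CD94, was lower by -6.46 ± 0.33 and the inhibitory NK receptor gene Klra5 by -6.15 ± 0.18. The chemokine Ccl5 was lower by -5.08 ± 0.23. In all, 2051 of 16667 genes passed the threshold, 1082 higher and 969 lower in iNKT17 cells, and 521 of them changed at least 2-fold; without B6 ROR- replicate 1 the count was 1341.

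The remaining genes among the 10 largest rises were Pram1 (4.95), the peptide transporter Slc15a3 (4.93), Abi3bp (4.92), the protease inhibitor Serpinb1a (4.53), the signalling adaptor Clnk (4.51), the Src-family kinase Blk (4.27) and the carboxypeptidase Cpe (4.07). The remaining falls were Ly6c2 (-5.44), Ifitm2 (-5.10), Ms4a4b (-4.68), the chemokine Xcl1 (-4.64), the cytotoxic granule gene Nkg7 (-4.51), Plac8 (-4.49) and Klrc1 (-4.21). Their adjusted p-values ran from 1.17e-08 for Klra5 to 2.67e-04 for Il22, and each of these 20 genes stayed past the threshold whichever array was left out. Cpe in ROR- cells of B6, and Klra5, Ly6c2, Ms4a4b and Klrc1 in iNKT17 cells of BALB/c, also had means below the dim level; over the whole comparison this held for 12 of the 87 named calls. On 1 ROR- array, BALB/c replicate 2, type 17 genes stood higher than on the others of its group: the mean of the type 17 list was 7.01 there and 6.34 and 6.35 on the other BALB/c ROR- arrays, and Il22 read 5.46 against at most 2.96 on the other ROR- arrays. Il23r read 7.0 there against 3.05 and 3.37 on the other BALB/c ROR- arrays, and Il1r1 7.0 against 4.97 and 5.25. Without this array Il23r stood at 6.70 and Il22 at 5.90 as the mean of both strains. Its Klrd1 level, 10.18, lay among those of the other ROR- arrays, 9.90 to 10.42.

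**Figure D2:**
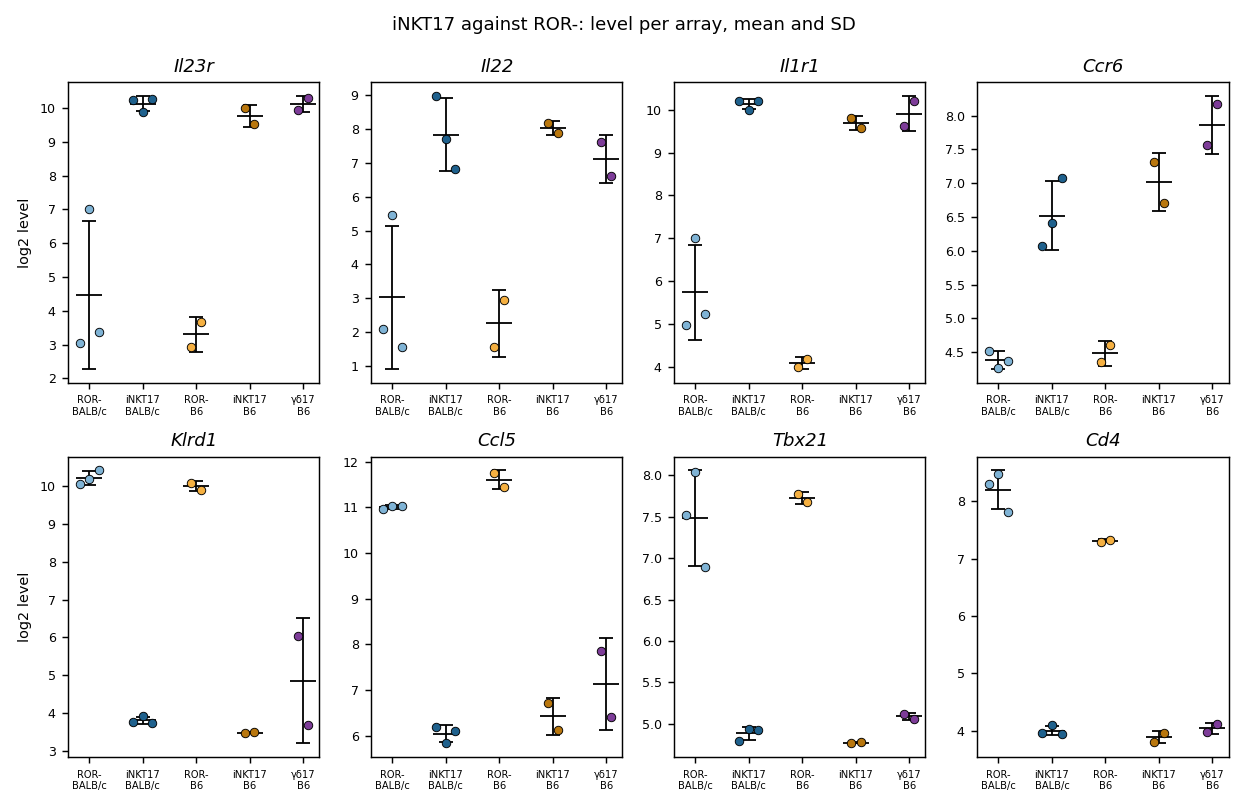
Log2 level of 8 genes on each of the 12 arrays, by group; points are arrays, the horizontal mark is the group mean and the bars its SD (n = 3 in BALB/c, n = 2 in B6). Il23r, Il22, Il1r1 and Ccr6 were higher in both iNKT17 groups than in the ROR- group of their strain, and Klrd1, Ccl5, Tbx21 and Cd4 lower.

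Of the 29 tested members of the type 17 list, 20 rose, 1 fell and 8 did not pass the threshold (21 higher and 2 lower when adjusted over the list alone). The chemokine receptor Ccr6 rose by 2.34 ± 0.20, Sdc1, the syndecan that marks iNKT17 cells, by 2.20 ± 0.36, and Il17a itself by 1.43 ± 0.30. The list was higher as a set (camera adjusted p = 1.39e-17); its adjusted p = 0.107 with an estimated correlation. Il17a lost its call without B6 ROR- replicate 1, where it stood at 1.23 with an adjusted p of 0.051.

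The type 1 and cytotoxic list moved the other way, with 24 of 30 members lower and 1 higher (25 and 2 when adjusted over the list alone). Tbx21, the transcription factor T-bet, was lower by -2.78 ± 0.17, Ifng by -3.75 ± 0.58, the granzyme Gzma by -3.71 ± 0.56 and the interleukin 2 receptor chain Il2rb by -1.76 ± 0.21. Gzma and Klra9 lie below the dim level in both iNKT17 groups, so the sizes of their falls are uncertain. This list kept its call with an estimated correlation (camera adjusted p = 5.95e-27, and adjusted p = 0.0191 with an estimated correlation), the only list of this comparison to do so. Of the 13 tested markers of conventional NK and CD8 cells, 8 fell and 0 rose (9 and 0 when adjusted over the list alone). Among them were Fcer1g (-3.64), Klra9 (-2.45) and Tyrobp (-1.74); camera gave an adjusted p of 1.66e-06 for the list and an adjusted p = 0.107 with an estimated correlation. In the Klra and Klrb families, Klrb1f rose (1.69) while Klra5, Klra9 and Klrb1c (-1.38) fell; 2 of the 5 tested members were higher and 3 lower, the same numbers when adjusted over the list alone, and the set did not pass (camera adjusted p = 0.0909).

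In the type 2 list 10 of 19 members were lower and 1 higher (12 and 2 when adjusted over the list alone). The members with the largest falls beside Plac8 were Lef1 (-3.43), Izumo1r, the folate receptor 4 gene (-3.20), and the interleukin 6 receptor Il6ra (-2.13). The cytokine Il4 was lower by -1.17 ± 0.13 and the transcription factor Gata3 by -0.59 ± 0.13, with Gata3 losing its call without B6 ROR- replicate 1 (-0.50, adjusted p = 0.053). Zbtb16, which encodes the iNKT lineage factor PLZF, did not differ detectably (-0.37 ± 0.13, adjusted p = 0.0904), though without either gamma-delta 17 array, which enter this comparison only through the spread, it passed (adjusted p = 0.038). Camera placed the type 2 list lower (adjusted p = 1.82e-07; adjusted p = 0.148 with an estimated correlation).

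Genes that respond to TCR signals were mostly lower in iNKT17 cells. In that list 15 of 29 members fell and 1 rose (17 and 2 when adjusted over the list alone), with Spry2 at -2.11, Myc at -1.83, Tnfrsf4 at -1.76 and, among the anchor genes, Cd5 at -1.31 ± 0.11. The member that rose was Pdcd1, the PD-1 receptor gene, at 2.52 ± 0.12. Camera gave an adjusted p of 5.41e-08, and an adjusted p = 0.119 with an estimated correlation. Egr2 was lower by -0.68 ± 0.15, a call lost without B6 ROR- replicate 1 (-0.67, adjusted p = 0.052) or B6 iNKT17 replicate 1 (-0.60, 0.061). Nr4a1 stood at -0.60 ± 0.21 and did not pass (adjusted p = 0.0999), but did so without BALB/c ROR- replicate 1 (-0.71, 0.048).

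S1pr1, the receptor that lets lymphocytes leave tissue, was lower in iNKT17 cells by -4.04 ± 0.27. In the egress, residency and homing list 12 of 27 members fell and 5 rose, the same numbers when adjusted over the list alone. Among those that fell were Rgs2 (-1.68), Cxcr4 (-1.59) and Klf2, the transcription factor that drives S1pr1 (-1.75 ± 0.40), whose call was lost without B6 iNKT17 replicate 2 (-1.67, adjusted p = 0.057). Camera placed this list lower (adjusted p = 0.0254; adjusted p = 0.474 with an estimated correlation), a call lost without BALB/c ROR- replicate 1 (adjusted p = 0.0513).

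Most alpha-beta T cell genes tested were lower in iNKT17 than in ROR- cells, while gamma-delta T cell genes went both ways. Of 12 alpha-beta and iNKT genes 7 fell and 1 rose (8 and 1 when adjusted over the list alone), with Slamf6 at -3.99, the coreceptor gene Cd4 at -3.81 ± 0.12 and Themis at -2.15 (camera adjusted p = 5.01e-05; adjusted p = 0.175 with an estimated correlation). Of 9 gamma-delta genes 5 rose and 1 fell (5 and 2 when adjusted over the list alone), with Blk, the scavenger receptor gene 5830411N06Rik (2.3), Maf (1.84) and Cd163l1 (1.04) leading the rises (camera adjusted p = 0.0421; adjusted p = 0.572 with an estimated correlation). The gamma-delta list shares members, Cd163l1 among them, with the list that holds Il17a, so its rises are not independent of that list's. Cd163l1 lost its call without B6 ROR- replicate 2 (0.91, adjusted p = 0.064) or B6 iNKT17 replicate 1 (1.01, 0.051). The gamma-delta call was lost without BALB/c ROR- replicate 1 (adjusted p = 0.0605) or 3 (0.0857), BALB/c iNKT17 replicate 3 (0.0553), B6 ROR- replicate 2 (0.0878) or B6 iNKT17 replicate 1 (0.0733), and with each array centred on its median (0.075), the stricter dim filter (0.0959), array weights (0.0542) or the replicate block (0.0575). Of 14 immature thymocyte markers 5 fell and 1 rose, the same numbers when adjusted over the list alone; Cd4 and Themis are also in this list, and Aqp11 (-1.87) and Satb1 (-1.75) fell as well (camera adjusted p = 0.00784; adjusted p = 0.449 with an estimated correlation). Aqp11 in both iNKT17 groups and Slamf6 in B6 iNKT17 cells lie below the dim level, so the sizes of their falls are uncertain.

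Interferon-stimulated genes were lower, with 12 of 28 members down and 0 up (16 and 0 when adjusted over the list alone). Oas3 (-1.18), Ifit2 (-1.09) and Ifit1 (-0.75) were among them, and camera gave an adjusted p of 1.36e-06, with an adjusted p = 0.107 with an estimated correlation. In the MHC list 4 of 24 genes fell, the same number when adjusted over the list alone, among them H2-DMa (-0.86) and H2-T24 (-0.70); the set did not pass (camera adjusted p = 0.0592). Of the 26 cytokine and chemokine ligands 6 were higher and 5 lower (6 and 6 when adjusted over the list alone; camera adjusted p = 0.579).

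Proliferation genes did not differ gene by gene. None of the 38 cell cycle genes passed limma's threshold, over all genes or when adjusted over the list alone, and Mki67 stood at 0.80 ± 0.51 (adjusted p = 0.399), while camera placed the list higher (adjusted p = 0.00218; adjusted p = 0.742 with an estimated correlation). The cell cycle call was lost without BALB/c iNKT17 replicate 2 (adjusted p = 0.115), B6 ROR- replicate 1 (0.129) or B6 iNKT17 replicate 2 (0.0776). The survival genes went both ways. Of 20 pro-apoptotic genes 2 rose and 2 fell (4 and 4 when adjusted over the list alone), with the death ligand Fasl at -3.33, Bcl2l11, which encodes BIM, at -0.67 ± 0.08 and Bik at 0.82. Of 14 anti-apoptotic genes 1 rose and 2 fell (1 and 3 when adjusted over the list alone), with Pim1 at -1.0 and Traf1 at -0.85, and Bcl2 did not pass (-0.75 ± 0.23, adjusted p = 0.0557) except without BALB/c ROR- replicate 2 (-0.85, 0.041) or BALB/c iNKT17 replicate 2 (-0.92, 0.0069). Camera gave adjusted p-values of 0.717 and 0.563 for these lists.

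Metabolic and housekeeping lists held few calls. Of 32 oxidative phosphorylation genes 3 rose, Ndufa1 (0.54), Ndufa4 (0.39) and Uqcrb (0.36), the same number when adjusted over the list alone (camera adjusted p = 0.00121; adjusted p = 0.534 with an estimated correlation), and each of the 3 lost its call without B6 ROR- replicate 1. Of 34 ribosomal protein genes 2 fell, Rps14 (-0.45) and Rps19 (-0.36), and 1 when adjusted over the list alone (camera adjusted p = 5.01e-05; adjusted p = 0.142 with an estimated correlation). Of 17 glycolysis genes 2 fell, the same number when adjusted over the list alone, among them the glucose transporter Slc2a3 (-0.80; camera adjusted p = 0.879), and of 18 lipid and cholesterol genes 2 rose and 2 fell (5 and 3 when adjusted over the list alone; camera adjusted p = 0.264). Among 22 immediate-early and heat-shock genes Ier3 fell (-1.99), the only call over all genes or over the list alone, and camera placed the list lower (adjusted p = 0.022; adjusted p = 0.742 with an estimated correlation), a call lost without BALB/c ROR- replicate 2 (adjusted p = 0.261), BALB/c iNKT17 replicate 2 (0.0624) or 3 (0.0639), or B6 ROR- replicate 2 (0.0876).

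Markers of cells outside the T lineage were mostly unchanged. The neutrophil and erythroid lists held 0 calls among 10 and 4 tested genes, over all genes or over the list alone (camera adjusted p = 0.624 for both). The macrophage, monocyte and dendritic list held 1 rise among 16 genes, Cst3 (0.32), and the epithelial and stromal list 1 fall among 17, Cdh1 (-0.41), with 1 and 0 when adjusted over the list alone (camera adjusted p = 0.942 and 0.624). Of 7 B cell genes, Cd79b rose (1.76) and Ighm (-0.67) and Cd79a (-0.43) fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.806). In this comparison the list median and camera's direction differed in sign for pro-apoptotic genes (median 0.02), glycolysis (median 0.08) and macrophage markers (median -0.02), and the mean of the B cell list, 0.09, was opposite in sign to its median, -0.03; none of these lists passed camera. Rps14, Cd79a, Ighm, Cst3 and Cdh1 each lost their call without B6 ROR- replicate 1, B6 ROR- replicate 2 or other single arrays, with adjusted p-values of up to 0.18, 0.20, 0.074, 0.067 and 0.14.

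Within BALB/c, 676 genes were higher and 485 lower in iNKT17 than in ROR- cells, and within B6, 472 were higher and 526 lower. The leading genes of the mean comparison moved in the same direction in both: Il23r by 5.66 ± 0.77 in BALB/c and 6.46 ± 0.95 in B6, Il22 by 4.81 ± 0.87 and 5.79 ± 1.06, Klrd1 by -6.41 ± 0.42 and -6.51 ± 0.51, and Tbx21 by -2.60 ± 0.22 and -2.95 ± 0.27. The sizes for Il23r and Il22 are uncertain, since Il22 in both ROR- groups and Il23r in B6 ROR- cells lie below the dim level. They also depend on BALB/c ROR- replicate 2, where both read high: without it the BALB/c values were 6.93 for Il23r and 6.02 for Il22, with 5.43 for Pram1 and 5.53 for Abi3bp. Without BALB/c ROR- replicate 1 Il23r stood at 4.95 in BALB/c, and without replicate 3 Il22 at 4.07. Clnk (4.91), Pram1 (4.79), Abi3bp (4.73), Plac8 (-4.56) and Ly6c2 (-5.13) also led in BALB/c, and Slc15a3 (5.43), Cpe (5.13) and Ifitm2 (-5.90) in B6; Ly6c2 in BALB/c iNKT17 and Cpe in B6 ROR- cells lie below the dim level. The genes called in both strains comprised 356 higher in both and 322 lower in both, against 19.1 and 15.3 expected from independent lists, and 0 called in opposite directions. The log2 fold changes of the strains correlated at r = 0.82 across genes, which are not independent replicates. In B6, Il22 was not past the threshold without B6 ROR- replicate 1 (5.09, adjusted p = 0.079) and stood at 6.48 without B6 ROR- replicate 2. Without that array the B6 count was 492, without B6 ROR- replicate 2 it was 657, without B6 iNKT17 replicates 1 and 2 it was 592 and 529, and without BALB/c iNKT17 replicate 3 the BALB/c count was 742.

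The difference between the strains in this cell-type difference passed limma's threshold for 14 genes, 10 with a higher (more positive or less negative) and 4 with a lower value of iNKT17 minus ROR- in BALB/c, and 669 genes had an unadjusted p under 0.05, or 4.01% of the genes tested, fewer than the 5% expected with no difference. Gpnmb (2.86 ± 0.26, adjusted p = 0.00334) stood at 7.30 in B6 ROR- cells and between 3.71 and 4.44 in the other iNKT17 and ROR- groups. It fell from ROR- to iNKT17 cells in B6. In BALB/c ROR- cells its mean of 3.71 was already little above the dim level of 3.45, so a fall there could hardly be seen. Klra9 (3.56 ± 0.41, adjusted p = 0.0134), an NK receptor gene, stood at 6.91 ± 0.05 (SD, n = 2) in B6 ROR- cells and at 2.94 ± 0.66 (n = 3) in BALB/c ROR- cells. Its means of 2.94, 2.28 and 2.69 in BALB/c ROR-, BALB/c iNKT17 and B6 iNKT17 cells lie below the dim level of 3.45, so the sizes of its differences, here and in the other comparisons, are uncertain. The chemokine Cxcl3 had a negative value (-3.15 ± 0.48), with 9.24 in B6 iNKT17 and 5.07 in BALB/c iNKT17 cells; its BALB/c ROR- mean of 3.21 is below the dim level, so this size is uncertain too. Gimap4 (2.05), Klri2 (1.67), Ifit1bl1 (1.62), Frmd5 (-2.29), the adhesion receptor Cd2 (-1.91) and the keratin Krt24 (-1.79) completed the genes named by the rule. The means of Klri2 and Ifit1bl1 lay below the dim level in iNKT17 cells of both strains, and that of Klri2 also in BALB/c ROR- cells (3.39). None of these 9 calls survived all omissions of single arrays, and the count fell to 0 without B6 ROR- replicate 2 and to 2 with the replicate block. With quantile normalization 8 genes were higher and 1 lower, against 10 and 4. The anchor genes Tbx21, Il17a, Il23r and Zbtb16 had interaction values of 0.35 ± 0.34, 0.42 ± 0.60, -0.80 ± 1.22 and 0.52 ± 0.25, each with an adjusted p of 0.999.

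The next comparison asked how iNKT17 cells differ between the strains. Gbp2b, a guanylate-binding protein gene, was higher in BALB/c iNKT17 cells by 4.16 ± 0.28 and the protease cathepsin E gene Ctse by 4.09 ± 0.21. The NK receptor gene Klrb1b was lower in BALB/c by -4.27 ± 0.16, the chemokine Cxcl3 by -4.17 ± 0.34, and Trim34a and Trim12a, neighbouring genes of the tripartite motif family, by -3.17 ± 0.30 and -2.92 ± 0.36. Gbp2b averaged 3.36 in B6 iNKT17 cells, below the dim level, so the size of its difference is uncertain. Trim12a stood at -2.25 without B6 iNKT17 replicate 1 and at -3.60 without replicate 2. In all 112 genes were higher and 135 lower in BALB/c, 144 of them by at least 2-fold. Type 17 cytokine and receptor genes did not differ detectably, with Il17a at 0.10 ± 0.43, Il23r at 0.37 ± 0.86 and Ccr6 at -0.49 ± 0.28.

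The other leading genes higher in BALB/c iNKT17 cells were Pla2g7 (2.5), Msh5 (2.27), the matrix metalloproteinase Mmp14 (2.18), Ifi204 (2.11), Lhfpl3 (2.09), the dynein Dnah8 (2.06), Scg5 (2.04) and the hypoxia-responsive factor Epas1 (1.99). Pla2g7, Ifi204 and Lhfpl3 in B6 and Oasl2 in BALB/c iNKT17 cells also had means below the dim level. The leading genes lower in BALB/c were the histone genes H4c9 (-4.24) and H2bc9 (-2.50), the apolipoprotein Apoa2 (-2.59), Frmd5 (-2.48), H2-T10 (-2.44) and Krt24 (-2.31). Zbtb16 was higher in BALB/c by 0.98 ± 0.18 (adjusted p = 0.019), at 8.99 ± 0.09 (SD, n = 3) against 8.01 ± 0.16 (n = 2). It lost that call without BALB/c iNKT17 replicate 1 (1.03, adjusted p = 0.052) or replicate 3 (0.94, 0.085) or B6 iNKT17 replicate 1 (0.87, 0.13) or replicate 2 (1.10, 0.097). Nnt, a mitochondrial gene that C57BL/6J mice carry in a deleted form, was higher by 0.91 ± 0.15 (adjusted p = 0.00963), a call that ended without BALB/c iNKT17 replicate 3 (0.85, adjusted p = 0.051) or either B6 iNKT17 array (0.88, adjusted p = 0.08, without replicate 1, and 0.94, 0.093, without replicate 2). Ifi204, Scg5 and H2bc9 lost their calls without B6 iNKT17 replicate 2 as well, at adjusted p-values of 0.20, 0.28 and 0.42.

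By list, 3 of 24 members of the MHC list were lower and 1 higher in BALB/c iNKT17 cells, the same numbers when adjusted over the list alone. H2-T10, Nlrc5 (-1.28) and H2-K1 (-1.23) were lower and the class II gene H2-Ab1 (1.5) higher (camera adjusted p = 0.0478, and adjusted p = 0.705 with an estimated correlation). Nlrc5 is in the list but lies outside the MHC, on chromosome 8. MHC alleles differ between these strains by haplotype, and a probe set can read alleles unequally, which was not tested here. Oasl2 (-2.30, below the dim level in BALB/c) and Bst2 (-1.32) were the interferon-stimulated genes past the threshold, and Tnfsf8 (-1.38) the cytokine gene. Ccr4 (1.36) and Zbtb16 rose in the type 2 list, Crtam (1.25) in the egress list, Cd28 (1.40) with Zbtb16 in the alpha-beta list and Satb1 (1.67) among the thymocyte markers. Each of Bst2, Ccr4, Crtam, Cd28, Satb1 and H2-Ab1 lost its call without B6 iNKT17 replicate 2, at adjusted p-values of 0.27, 0.13, 0.42, 0.38, 0.093 and 0.41, and also without at least 1 other array. Tnfsf8 and Nlrc5 lost theirs without B6 iNKT17 replicate 1, at 0.07 and 0.067.

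At the preset correlation, camera placed cell cycle genes lower as a set in BALB/c iNKT17 cells. None of the 38 passed limma's threshold over all genes, and 37 did so when adjusted over the list alone, all lower, with a median of -1.86 (camera adjusted p = 8.70e-23; adjusted p = 0.705 with an estimated correlation). Over all genes 2103 had an unadjusted p under 0.05. The mean of the list was 5.48, 7.80 and 6.14 on BALB/c iNKT17 replicates 1, 2 and 3 and 7.96 and 8.75 on the B6 iNKT17 arrays. Beside this, the immediate-early and heat-shock list averaged 8.57 on BALB/c iNKT17 replicate 1 and between 7.29 and 7.45 on the other iNKT17 arrays. Without BALB/c iNKT17 replicate 2 the comparison gave 530 genes, without BALB/c iNKT17 replicate 1 or 3 it gave 132 or 112, and without B6 iNKT17 replicate 1 or 2 it gave 108 or 77; with the cell cycle mean as a covariate, chosen after the data were seen, it gave 90. Without the pair of BALB/c arrays highest in heat-shock genes it gave 109.

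**Figure D3:**
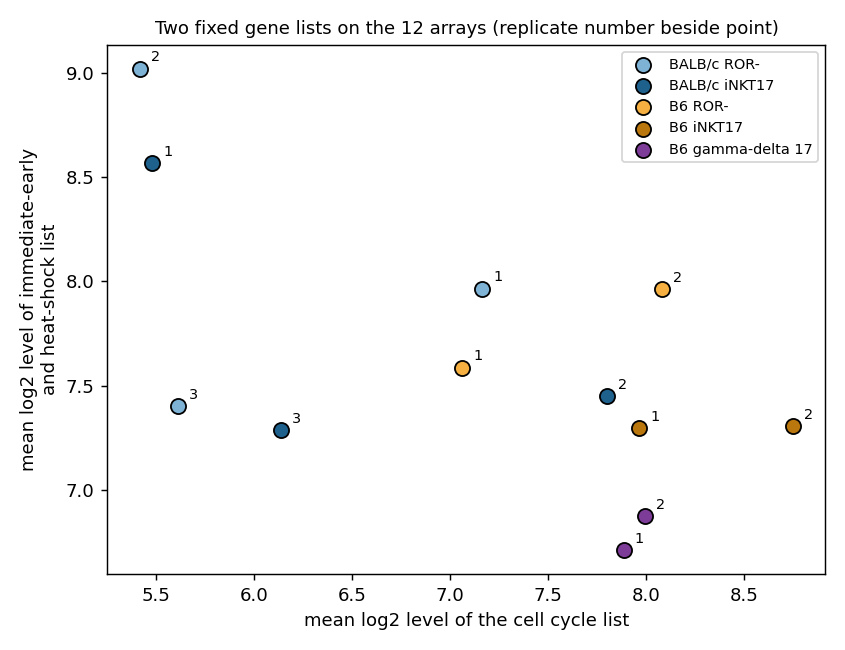
Mean log2 level of the cell cycle list against that of the immediate-early and heat-shock list on the 12 arrays; points are arrays, coloured by group with the replicate number beside each. BALB/c ROR- replicates 2 and 3 and BALB/c iNKT17 replicates 1 and 3 have cell cycle means of 5.42, 5.61, 5.48 and 6.14, below the lowest B6 array at 7.06.

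The remaining lists that camera called in this comparison held few single genes. The NK-complex list was lower (adjusted p = 0.0272; adjusted p = 0.509 with an estimated correlation), with 1 of 5 genes past the threshold over all genes and over the list alone, Klrb1b. The lipid list was lower (camera adjusted p = 0.01, and 0.737 with an estimated correlation). With the cell cycle covariate its direction turned and camera did not call it (adjusted p = 0.747). The type 17 and gamma-delta lists were higher (adjusted p = 0.0497 for both; adjusted p = 0.737 with an estimated correlation for both). These last 3 lists held 0 calls among 18, 29 and 9 genes, over all genes or over the list alone. Over the 12 omissions of 1 array the gamma-delta call was lost in 8, the type 17 call in 7, the MHC call in 6 and the lipid and NK-complex calls in 2 each. Without B6 iNKT17 replicate 2 the adjusted p was 0.123 for the lipid, 0.422 for the type 17 and 0.128 for the gamma-delta list. Without BALB/c iNKT17 replicate 3 it was 0.0584, 0.0893 and 0.0893 for these. Without BALB/c iNKT17 replicate 2 it was 0.0544 for the type 17 and gamma-delta lists, 0.0834 for the NK-complex and 0.119 for the MHC list. Without B6 iNKT17 replicate 1 it was 0.0584 for the gamma-delta, 0.0531 for the NK-complex and 0.21 for the MHC list. The type 17, gamma-delta and MHC calls also ended, with values up to 0.052, without BALB/c ROR- replicate 1 or 3 or either B6 ROR- array. The median of the conventional NK and CD8 list, 0.01, and its mean, -0.13, differed in sign here, and camera did not call it.

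In ROR- cells, the same strains differed by 63 genes higher and 140 lower in BALB/c, with 1990 genes at an unadjusted p under 0.05. Gbp2b (4.66 ± 0.28) and Ctse (3.10 ± 0.21) were again higher in BALB/c. Trim12a (-4.26 ± 0.36), the NK receptor genes Klra9 (-3.97 ± 0.29) and Klrb1b (-3.17 ± 0.16), Trim34a (-3.78 ± 0.30) and Gpnmb (-3.58 ± 0.18) were lower. The other leading rises were Rnf32 (2.27), Dnah8 (2.07), Zfp868 (1.92), the meiotic gene Sycp1 (1.82), Msh5 (1.81), Zfp459 (1.81), Tpm3 (1.76) and Scp2 (1.54), and the other falls were H2bc9 (-2.92), Trim30d (-2.44), Apol7e (-2.38), H4c9 (-2.36) and the NK receptor gene Klre1 (-2.27). The sizes are uncertain for Gbp2b, Sycp1 and Zfp459, whose B6 ROR- means lie below the dim level, and for Klra9, Trim30d, Klri2 and Oasl2, whose BALB/c ROR- means do. H4c9 stood at -3.27 without B6 ROR- replicate 1 and at -1.45 without replicate 2. H4c9 and H2bc9 lost their calls without B6 ROR- replicate 2 (adjusted p = 0.50 and 0.29), as did Rnf32 (0.16) and Zfp459 (0.058). Sycp1 lost its call without B6 ROR- replicate 1 (0.052). The count was 78 without B6 ROR- replicate 1, 68 without B6 ROR- replicate 2, 132 without BALB/c ROR- replicate 3, 118 without the pair of BALB/c arrays highest in heat-shock genes and 115 with the cell cycle covariate.

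**Figure D4:**
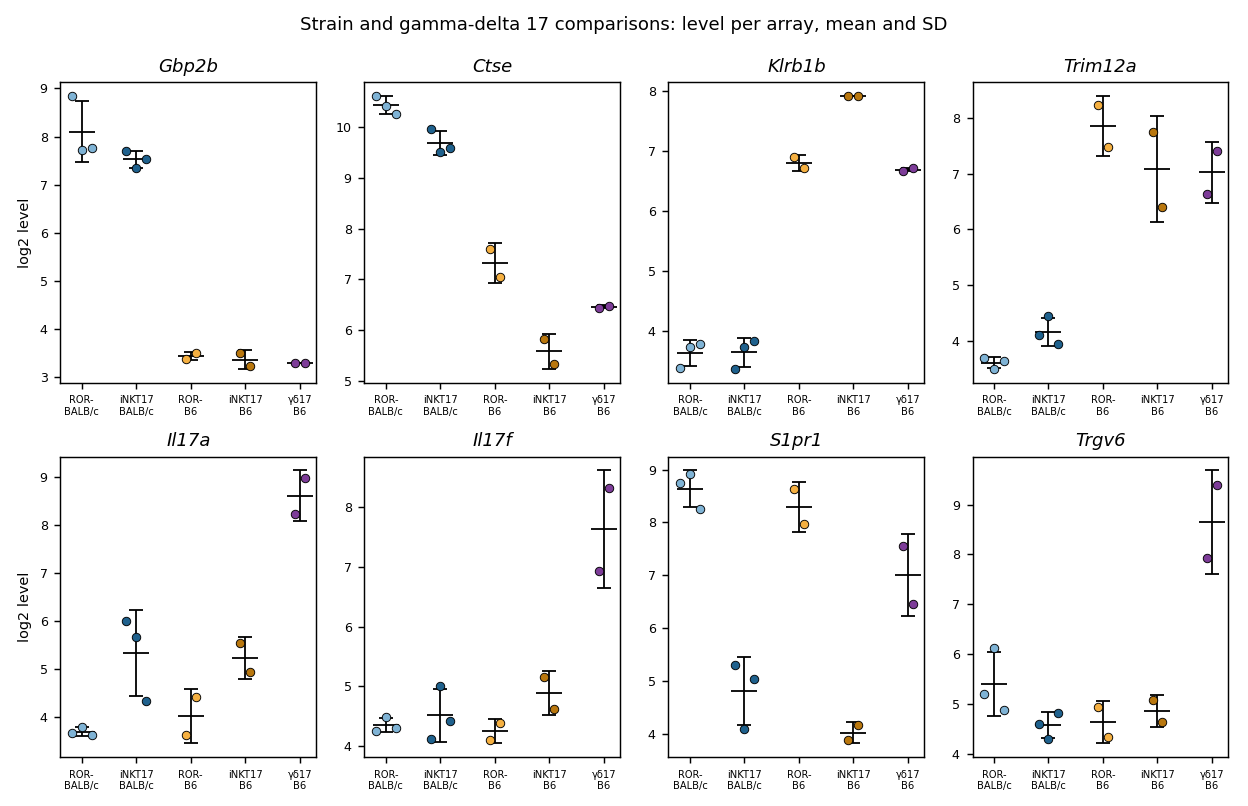
Log2 level of 8 genes on each of the 12 arrays, by group; points are arrays, the horizontal mark is the group mean and the bars its SD (n = 3 in BALB/c, n = 2 in B6). Gbp2b and Ctse were higher and Klrb1b and Trim12a lower in both BALB/c groups, and Il17a, Il17f, S1pr1 and Trgv6 were higher in B6 gamma-delta 17 than in B6 iNKT17 cells.

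Some NK receptor genes were lower in BALB/c than in B6 ROR- cells, but Klrd1 was not, at 10.06, 10.18 and 10.42 on the BALB/c and 10.09 and 9.90 on the B6 ROR- arrays. Of the 5 tested members of the Klra and Klrb families 3 were lower, the same number when adjusted over the list alone: Klra9, Klrb1b and Klrb1c, which encodes NK1.1 (-2.25). This list kept its camera call with an estimated correlation (camera adjusted p = 3.36e-08, and adjusted p = 0.014 with an estimated correlation). In the type 1 and cytotoxic list 6 of 30 genes were lower and 0 higher (11 and 0 when adjusted over the list alone), among them Klre1, Klrb1c, Klri2 (-1.67, below the dim level in BALB/c) and Fasl (-1.47), with a camera adjusted p of 1.54e-08 and an adjusted p = 0.214 with an estimated correlation. Klrb1c and Fasl lost their calls without B6 ROR- replicate 1 (adjusted p = 0.085 and 0.17). Of 13 conventional NK and CD8 markers 3 were lower, the same number when adjusted over the list alone, among them Fcer1g (-1.60; camera adjusted p = 0.00893; adjusted p = 0.453 with an estimated correlation). Alleles of these receptor families differ between the strains, so a probe set can read them unequally. Tbx21 (-0.24 ± 0.24) and Ifng (-0.10 ± 0.82) did not differ detectably.

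Cd4 was higher in BALB/c ROR- cells (0.88 ± 0.17, adjusted p = 0.031), the only 1 of 12 alpha-beta genes past the threshold over all genes, with 3 higher when adjusted over the list alone (camera adjusted p = 0.00409; adjusted p = 0.453 with an estimated correlation); it lost its call without either B6 ROR- array (0.87, adjusted p = 0.19, and 0.90, 0.22). H2-T10 (-2.27), H2-K1 (-1.14) and Nlrc5 (-0.94), which lies outside the MHC, were the 3 members of the MHC list lower among 24. The number was the same when adjusted over the list alone (camera adjusted p = 0.0125, and adjusted p = 0.453 with an estimated correlation). Oasl2 (-1.56, below the dim level in BALB/c) was the interferon-stimulated gene among 28 (camera adjusted p = 1.77e-04, and adjusted p = 0.342 with an estimated correlation). The receptor genes Il21r (-1.80) and Il4ra (-0.84) were lower. Nlrc5, Oasl2, Il21r and Il4ra lost their calls without B6 ROR- replicate 2 (adjusted p = 0.20, 0.18, 0.16 and 0.26) and H2-K1 without B6 ROR- replicate 1 (0.071). Camera also placed the cell cycle (adjusted p = 1.34e-13), oxidative phosphorylation (5.29e-06), pro-apoptotic (0.026) and lipid (0.017) lists lower in BALB/c. With an estimated correlation the adjusted p was 0.453 for the first 3 of these and 0.513 for lipid genes. With the cell cycle covariate the lipid list turned direction (camera adjusted p = 0.962). The oxidative phosphorylation (0.129), pro-apoptotic (0.0622) and interferon (0.0648) lists then lost their calls. The cell cycle mean was 7.16, 5.42 and 5.61 on BALB/c ROR- replicates 1, 2 and 3 and 7.06 and 8.08 on the B6 ROR- arrays, so replicate 1 lay above a B6 array, and replicate 2 had the highest heat-shock mean of the 12 arrays (9.02). None of the 38 cell cycle genes, 32 oxidative phosphorylation genes or 18 lipid genes passed over all genes or over the list alone, and Fasl was the pro-apoptotic gene that did (2 lower and 1 higher when adjusted over the list alone). Without B6 ROR- replicate 2 the pro-apoptotic and lipid lists had adjusted p-values of 0.154 and 0.335, and without BALB/c ROR- replicate 3 both had 0.081. The MHC list had 0.144 without B6 ROR- replicate 1 and 0.082 without BALB/c ROR- replicate 1. In the B cell list the median, 0.08, was opposite in sign to the mean, -0.16, and to camera's direction, and camera did not call the list (adjusted p = 0.674).

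As the mean of both cell types, 299 genes were higher and 465 lower in BALB/c, led by Gbp2b (4.41, below the dim level in both B6 groups), Ctse (3.60), Dnah8 (2.06), Msh5 (2.04) and Rnf32 (1.95) and by Klrb1b (-3.72), Trim12a (-3.59), Trim34a (-3.47), H4c9 (-3.30) and Prr11 (-2.73). Nnt was higher by 0.78 ± 0.10 and Zbtb16 by 0.72 ± 0.13. In the cell cycle list 9 of 38 genes were lower and 38 when adjusted over the list alone, with Kif11 (-2.62), Rrm2 (-2.56), Bub1 (-2.36) and Cdk1 (-2.32) in front (camera adjusted p = 2.64e-22; adjusted p = 0.418 with an estimated correlation). Genes called in both cell types comprised 35 higher in both and 54 lower in both, against 0.423 and 1.13 expected from independent lists, and 0 called in opposite directions; the fold changes correlated at r = 0.67 across genes. The count of 764 became 288 without B6 iNKT17 replicate 2, 303 without B6 ROR- replicate 2, 454 and 419 without BALB/c iNKT17 replicates 1 and 3, 363 without the pair of BALB/c arrays highest in heat-shock genes, 160 with the cell cycle covariate and 1115 without BALB/c iNKT17 replicate 2.

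The last main comparison set iNKT17 cells against gamma-delta 17 cells, both producers of interleukin 17, in B6 mice. Gamma-delta 17 cells had more Il17a and Il17f, which were lower in iNKT17 cells by -3.38 ± 0.47 and -2.75 ± 0.39. Il17a stood at 8.61 ± 0.53 (SD, n = 2) in gamma-delta 17 cells and at 5.23 ± 0.43 in iNKT17 cells. The receptor segment Trgv6 (-3.79 ± 0.46), the scavenger receptor Cd163l1 (-3.75 ± 0.37) and S1pr1 (-2.98 ± 0.42) were also lower in iNKT17 cells. The chemokine Cxcl3 (4.47 ± 0.38) and Ctla2b (2.53 ± 0.27) were higher. Il23r (-0.36 ± 0.95), Il1r1 (-0.22 ± 0.49) and Ccr6 (-0.85 ± 0.31) did not differ detectably.

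By limma 28 genes passed the threshold, 10 higher and 18 lower in iNKT17 cells, and 1417 had an unadjusted p under 0.05. With only the arrays of these groups fitted 2 of the 28 passed and no other gene, and with the replicate block 13 of them and no other. The other leading genes higher in iNKT17 cells were App (2.04), the toll-like receptor genes Tlr7 (1.65) and Tlr6 (1.04), Irs2 (1.25), Klrb1b (1.22), Glyat (1.19) and Ralb (1.09). The others lower were Klf3 (-2.65), Ms4a6b (-1.97), the inflammatory caspase Casp1 (-1.83, with a mean below the dim level in iNKT17 cells), Auts2 (-1.81) and Csn3 (-1.63), with the gut-homing receptor Ccr9 (-1.38). Without any 1 of the 12 arrays Cxcl3, Ctla2b, Cd163l1, Klf3 and Csn3 kept their calls, and the other 15 named genes did not. Without B6 iNKT17 replicate 2 the count was 5, with Il17a at -3.07 (adjusted p = 0.28), Il17f at -2.49 (0.28), S1pr1 at -3.12 (0.18) and Trgv6 at -3.57 (0.13). It was 11 without B6 iNKT17 replicate 1 and 55 without gamma-delta 17 replicate 2. Without gamma-delta 17 replicates 1 and 2 in turn, Trgv6 stood at -4.52 and -3.06, Cd163l1 at -4.5 and -3.0 and Il17f at -3.44 and -2.05. Without gamma-delta 17 replicate 1 the count was 63, and Il4, at 1.07 ± 0.20 with an adjusted p of 0.0842, then stood at 1.36 with an adjusted p of 0.021.

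By list, 3 of 29 type 17 genes were lower in iNKT17 cells and 0 higher, the same numbers when adjusted over the list alone: Il17a, Il17f and Cd163l1 (camera adjusted p = 0.324). Of 9 gamma-delta genes 2 were lower, Trgv6 and Cd163l1, and 4 when adjusted over the list alone (camera adjusted p = 2.24e-04; adjusted p = 0.448 with an estimated correlation). None of the 12 alpha-beta genes passed over all genes and 3 were higher when adjusted over the list alone; the list median was -0.06 and its mean 0.39, and camera followed the mean (adjusted p = 0.0418; adjusted p = 0.50 with an estimated correlation). Of the type 2 genes 0 of 19 passed over all genes, and 6 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0114; adjusted p = 0.50 with an estimated correlation). Without gamma-delta 17 replicate 2 the alpha-beta list turned to the other direction (adjusted p = 0.462) and the type 2 list had 0.764. Without B6 iNKT17 replicate 1 they had 0.12 and 0.0564, and the alpha-beta call also ended without any 1 of the 3 BALB/c ROR- arrays, at up to 0.0779.

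On gamma-delta 17 replicate 1, markers of neutrophils and CD8 T cells were bright. S100a9 read 9.0 there and at most 3.98 on the other 11 arrays, Lyz2 6.86 against 3.82, Cd8a 8.76 against 6.74 and Cd8b1 8.24 against 6.33; Klrd1 read 6.03, against 3.69 on the other gamma-delta 17 array. Camera placed the neutrophil, immature thymocyte, conventional NK and CD8, and type 1 lists lower in iNKT17 cells (adjusted p = 0.00913, 0.0114, 0.0195 and 0.00913; adjusted p = 0.50 with an estimated correlation for each). Without this array their adjusted p-values were 0.874, 0.141, 0.628 and 0.608, and the first 3 turned to the other direction; the neutrophil list also lost its call without B6 iNKT17 replicate 1 (0.0702). Of these lists only the thymocyte list held a call over all genes, Ccr9, and adjusted over the list alone the numbers lower were 0 of 10, 1 of 14, 3 of 13 and 1 of 30.

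Camera called 9 further lists in this comparison, with 1 call over all genes among them, Klrb1b; adjusted over the list alone, 3 TCR genes were higher, 2 B cell genes lower and Klrb1b higher. The B cell (adjusted p = 0.0142) and macrophage lists (0.0418) were lower in iNKT17 cells. The NK-complex list (0.0114), immediate-early and heat-shock genes (0.00913), the cell cycle, pro-apoptotic, glycolysis and oxidative phosphorylation lists (0.0195 for each) and the TCR list (0.0197) were higher. With an estimated correlation the adjusted p = 0.285 for the B cell and NK-complex lists, 0.416 for macrophage markers, 0.50 for the pro-apoptotic, TCR and glycolysis lists, 0.588 for the heat-shock and oxidative phosphorylation lists and 0.715 for the cell cycle. The cell cycle list reversed its direction without B6 iNKT17 replicate 2 (adjusted p = 0.997), and without gamma-delta 17 replicate 2 the NK-complex list had 0.241 and the B cell list 0.144. Of the 12 omissions 3 ended the cell cycle, glycolysis and macrophage calls, 2 the pro-apoptotic, TCR and oxidative phosphorylation calls, and 1 the heat-shock, NK-complex and B cell calls; each was of a gamma-delta 17 or a B6 iNKT17 array.

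Against B6 ROR- cells, gamma-delta 17 cells differed in 1003 genes, 435 higher and 568 lower. Il23r (6.83 ± 0.95), Il1r1 (5.81 ± 0.49), Abi3bp (5.60 ± 0.61), Pram1 (5.08 ± 0.50) and Serpinb1a (5.05 ± 0.46) rose most, Il17a rose by 4.60 ± 0.47 and Ccr6 by 3.38 ± 0.31. Klra5 (-6.33 ± 0.28), Ly6c2 (-5.75 ± 0.81), Klrd1 (-5.13 ± 0.51), Ctla2b (-5.11 ± 0.27) and Klrc1 (-4.68 ± 0.29) fell most. Il23r in ROR- cells and Klra5 in gamma-delta 17 cells have means below the dim level, so their sizes are uncertain. The falls were smaller on gamma-delta 17 replicate 1, the array with neutrophil and CD8 genes: without it Ly6c2 stood at -7.55, Klra5 at -6.93 and Klrd1 at -6.31, and without replicate 2 at -3.95, -5.72 and -3.96. Zbtb16 was lower by -0.99 ± 0.20 (adjusted p = 0.00996) and Il4 by -2.14 ± 0.20. Of the type 17 genes 16 of 29 rose and 1 fell (19 and 1 when adjusted over the list alone), and of the type 1 genes 22 of 30 fell (24 lower and 1 higher when adjusted over the list alone). The type 1 list had a camera adjusted p of 3.23e-26 and an adjusted p = 0.0208 with an estimated correlation, and the type 17 list 5.24e-17 and an adjusted p = 0.0622 with an estimated correlation. The type 1 list averaged 6.11 on gamma-delta 17 replicate 1 and 5.47 on replicate 2.

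This comparison shares its ROR- arrays with iNKT17 minus ROR- in B6. The fold changes of the pair correlated at r = 0.83 across genes, against 0.50 in 100 simulated draws with no effect, and their covariance was 0.214 against 0.0241 simulated. Genes called in both comprised 291 higher in both and 373 lower in both, against 12.3 and 17.9 expected from independent lists, with 1 called in opposite directions. The simulated overlap of 0 is no yardstick for these counts, since draws with no effect give almost no calls in either comparison. With each comparison set against its own B6 ROR- array, a check chosen after the data were seen, the covariance was 0.176 (r = 0.59) with replicate 1 for iNKT17 and replicate 2 for gamma-delta 17 cells, and 0.206 (r = 0.78) the other way round. Genes called in both were then 144 higher and 189 lower, and 146 higher and 195 lower, against at most 4.27 and 6.28 expected from independent lists. The count of 1003 became 530 without B6 ROR- replicate 1, 564 without B6 ROR- replicate 2 and 650 without gamma-delta 17 replicate 2.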

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

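The tests on heat-shock genes, proliferation, probe mismatch, neutrophil RNA and thymocyte RNA were chosen only after the results were seen, as was the use of iNKT17 minus ROR- as a yardstick for neighbouring genes.

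The difference between iNKT17 and ROR- cells itself differed between the strains in 14 genes by limma's test of that difference. The values here are iNKT17 minus ROR- in BALB/c less the same in B6, on the log2 scale. For 5 genes a positive value marks a fall in B6 that was weaker or absent in BALB/c: Klra9 (3.56; -0.67 in BALB/c and -4.23 in B6), Gpnmb (2.86; 0.00 and -2.86), Gimap4 (2.05; -0.68 and -2.73), Klri2 (1.67; -0.32 and -1.99) and Ifit1bl1 (1.62; -2.12 and -3.75). Klra9, Klri2 and Ifit1bl1 lay below the dim level of 3.45 in iNKT17 cells of both strains, and Cxcl3 in BALB/c ROR- cells (3.21), so the sizes of their values are uncertain. In BALB/c ROR- cells Klra9 (2.94) and Klri2 (3.39) also lay below that level, and Gpnmb (3.71) little above it. A fall of these genes in BALB/c could therefore hardly be seen, and their values may reflect the strain difference in ROR- cells alone. The estimated rise was larger in BALB/c for BC064078 (1.88; 2.3 and 0.42) and Mmp14 (1.53; 1.90 and 0.37), and Epas1 (1.52; 1.30 and -0.23), Serpinb6b (1.57; 0.36 and -1.21) and Fcrl1 (1.41; 0.40 and -1.01) had estimates of opposite sign. Negative values belonged to Cxcl3 (-3.15; 1.87 and 5.02), Frmd5 (-2.29; 0.22 and 2.5) and Krt24 (-1.79; 0.31 and 2.10), whose rise was smaller in BALB/c, and to Cd2 (-1.91; -4.02 and -2.11), whose fall was larger. BC064078, Serpinb6b and Fcrl1 fall outside the rule for named genes and were chosen after their values were seen.

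Signal also appeared in data that the comparisons did not use. Of 12121 probe sets with several gene symbols or none, 160 passed the threshold for iNKT17 minus ROR- as the mean of both strains, 243 for BALB/c minus B6 as the mean of both cell types and 31 for iNKT17 minus gamma-delta 17. S100a8, which the dim filter removed, read 9.30 on gamma-delta 17 replicate 1 and between 2.14 and 2.44 on the other arrays.

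Other splits of the arrays were counted for 3 results. For iNKT17 minus ROR- as the mean of both strains, 1 of 60 splits within strain, the real one, gave as many genes (2051, against at most 25 in the others). A chance division of these samples is thus unlikely, though 1 of 60 is the smallest share that these splits can give. Chance between animals is not addressed, since the replicates may be technical. Within BALB/c the 10 splits are too few for a share under 0.05; the real one gave 1161 and the highest other 0. For BALB/c minus B6 as the mean of both cell types, 2 of 100 splits gave as many genes as the real one (764), a share under 0.05. But the split other than the real one gave more, 1004, so the share does not show that the strain label accounts for the count. That split sets BALB/c ROR- replicates 2 and 3 and iNKT17 replicates 1 and 3, the arrays with low cell cycle genes, against the rest, which points to a structure of the samples that the strain label does not hold.

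The cell cycle list was low on those 4 BALB/c arrays. A heat-shock response during handling is argued against as the whole cause, but by 1 array only. The bound asked for a cell cycle mean more than 1 log2 unit below the lowest B6 value of 7.06. It also asked for a heat-shock mean not above the highest of the B6 iNKT17 and ROR- arrays, 7.96. BALB/c ROR- replicate 3 met both, at 5.61 and 7.40. BALB/c iNKT17 replicate 3, at 6.14 and 7.29, lay below 7.06 but by less than the bound. A strain difference in proliferation stays open: the cell cycle mean differed by -1.69 between the strains, but that is the pattern itself and no test of its origin. Of the 2 other BALB/c arrays, ROR- replicate 1 (7.16) lay between the B6 ROR- arrays (7.06 and 8.08). BALB/c iNKT17 replicate 2 (7.80) lay above the lowest B6 array but below both B6 iNKT17 arrays (7.96 and 8.75). Within iNKT17 cells every BALB/c array thus lay below every B6 array, while within ROR- cells the strains overlapped. Age, sorting day and activation were not tested, since the labels do not give them.

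Gamma-delta 17 replicate 1 carried neutrophil and CD8 genes. Of the 14 measured neutrophil genes 42.9% were more than 1 log2 unit above every other array, against 0.0631% of all genes, so RNA from neutrophils may have been present; Ngp read 6.25 and Camp 5.36, while Ltf (3.89) stood near the highest other array (3.49). Of the 16 immature thymocyte genes 25% met the same bound. Cd8a and Cd8b1 are among them and would also be raised by CD8 T cells. They do not account for the whole share, since Dntt met the bound too (5.52, against at most 3.64 on the other arrays). Cd24a was also raised (5.97 against at most 4.41), but Rag2 (2.94) and Ptcra (4.94) were not. A sort for gamma-delta T cells would remove both cell types, and the labels describe no gate. No biological explanation was tested, since the design names none for a single array.

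The strain differences could be read through probes designed on the B6 sequence, which a BALB/c variant can only dim. By its direction alone, with no test needed, dimming leaves aside the genes higher in BALB/c (39.1% of the called genes); it stays open for the lower ones, of which 8 passed the test of the difference between cell types, and no probe sequence was at hand. Haplotype blocks that differ between the strains may place called genes side by side: 55 pairs of neighbouring genes were called in the same direction, against a mean of 17.8 in shuffled orders (permutation p = 1e-04, the smallest that 10000 shuffles can give). The ratio of that count to the shuffled mean was 3.10, and 5.22 (9 pairs) in iNKT17 and 8.97 (12 pairs) in ROR- cells, which by the prediction written before would speak for the explanation. It is left open because equally many genes of iNKT17 minus ROR-, which compares cells of the same strain, clustered no less, at ratios of 4.91, 9.86 and 10.27.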

How the results depend on the processing

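The alternatives with the cell cycle covariate and without the pair of BALB/c arrays highest in heat-shock genes were chosen after the data were seen. Over all alternatives, the 46 list calls gave 932 values on the same side of the threshold, 164 that lost it and 8 that reversed. The loss was uneven: 44 of the 46 were lost with an estimated correlation and 17 with the stricter dim filter. Of the 932 values, 478 came from leaving out single arrays, some of them outside the groups compared. The 287 named-gene results gave 6286, 582 and 0, with 19 that newly passed, and 82 sign turns where neither value was called. With eBayes trend and robust settings no list call and no count by more than 1.5 times changed. A count with a 2-fold minimum is smaller by construction, and a fit with fewer arrays or on the compared groups only has fewer samples; with the cell cycle covariate the loss of the 4 calls of the cell cycle list is fixed by construction, since the covariate is that list's mean, and says nothing about them. For every other change below the cause was not tested. An arm left with 1 array is assumed to vary like the other groups. The labels do not say whether the replicate numbers pair the samples. Same-number arrays correlated in their deviations from the group mean at -0.46, -0.34 and 0.14 for BALB/c ROR- with iNKT17. The values were 0.47 for B6 ROR- with iNKT17, and -0.01 and -0.12 for gamma-delta 17 with B6 ROR- and iNKT17. Different-number arrays of BALB/c ROR- and iNKT17 ran from -0.19 to 0.52, so the numbers do not mark pairs there. In the strain comparisons the block ties BALB/c to B6 arrays by number alone, so its counts show only how they depend on that choice.

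With quantile normalization the count was 9 for the interaction. The list adjusted p was then 0.0733 for pro-apoptotic in BALB/c minus B6 in ROR-. It was 0.162 for cell cycle, 0.088 for TCR, 0.0607 for glycolysis, 0.338 for oxidative phosphorylation, 0.0965 for alpha-beta and 0.132 for macrophage in iNKT17 minus gamma-delta 17. With each array centred on its median the list adjusted p was 0.075 for gamma-delta in iNKT17 minus ROR-. It was 0.252 for cell cycle, 0.0748 for TCR and 0.106 for alpha-beta in iNKT17 minus gamma-delta 17. With no dim filter the list adjusted p was 0.0577 for NK-complex in BALB/c minus B6 in iNKT17. With the stricter dim filter the list adjusted p was 0.0959 for gamma-delta in iNKT17 minus ROR-. It was 0.0544 for type 17, NK-complex and MHC and 0.0557 for gamma-delta in BALB/c minus B6 in iNKT17. It was 0.0932 for pro-apoptotic and 0.0823 for lipid in BALB/c minus B6 in ROR-. It was 0.0553 for type 2 and NK/CD8, 0.119 for cell cycle, 0.106 for pro-apoptotic and glycolysis, 0.0846 for TCR, 0.111 for oxidative phosphorylation, 0.13 for alpha-beta, 0.403 for macrophage and 0.245 for neutrophil in iNKT17 minus gamma-delta 17. With the mean of probe sets the list adjusted p was 0.0798 for gamma-delta in BALB/c minus B6 in iNKT17. It was 0.0556 for alpha-beta and B cell in iNKT17 minus gamma-delta 17. With array weights the count was 549 for BALB/c minus B6 in iNKT17 and 1159 for the mean strain difference. The list adjusted p was then 0.0542 for gamma-delta in iNKT17 minus ROR-. It was 0.0567 for MHC in BALB/c minus B6 in iNKT17. With a 2-fold minimum the count was 521 for iNKT17 minus ROR-, 478 for that difference in BALB/c, 582 for that difference in B6, 144 for BALB/c minus B6 in iNKT17, 126 for BALB/c minus B6 in ROR-, 215 for the mean strain difference and 580 for gamma-delta 17 minus ROR-. With only the groups compared the count was 82 for BALB/c minus B6 in ROR- and 2 for iNKT17 minus gamma-delta 17. The list adjusted p was then 0.11 for alpha-beta and 0.0512 for macrophage in iNKT17 minus gamma-delta 17. With the replicate block the count was 2 for the interaction, 371 for the mean strain difference and 13 for iNKT17 minus gamma-delta 17. The list adjusted p was then 0.0575 for gamma-delta in iNKT17 minus ROR-. It was 0.0724 for lipid in BALB/c minus B6 in ROR-. It was 0.0608 for alpha-beta in iNKT17 minus gamma-delta 17. Without the pair of BALB/c arrays highest in heat-shock genes the count was 732 for that difference in BALB/c, 2 for the interaction, 109 for BALB/c minus B6 in iNKT17, 118 for BALB/c minus B6 in ROR- and 363 for the mean strain difference. The list adjusted p was then 0.0582 for alpha-beta and 0.0535 for macrophage in iNKT17 minus gamma-delta 17. With the cell cycle covariate the count was 90 for BALB/c minus B6 in iNKT17, 115 for BALB/c minus B6 in ROR-, 160 for the mean strain difference and 47 for iNKT17 minus gamma-delta 17. The list adjusted p was then 0.973 for cell cycle and 0.087 for heat-shock in iNKT17 minus ROR-. It was 0.747 for type 17, cell cycle and lipid (reversed) and 0.383 for gamma-delta in BALB/c minus B6 in iNKT17. It was 0.984 for cell cycle (reversed), 0.0622 for pro-apoptotic, 0.0648 for interferon, 0.129 for oxidative phosphorylation and 0.962 for lipid (reversed) in BALB/c minus B6 in ROR-. It was 0.925 for cell cycle and 0.113 for oxidative phosphorylation in iNKT17 minus gamma-delta 17. With an estimated correlation the list adjusted p was 0.107 for type 17, interferon and NK/CD8, 0.148 for type 2, 0.742 for cell cycle and heat-shock, 0.119 for TCR, 0.474 for egress, 0.534 for oxidative phosphorylation, 0.572 for gamma-delta, 0.175 for alpha-beta, 0.142 for ribosomal and 0.449 for immature thymocyte in iNKT17 minus ROR-. It was 0.737 for type 17, lipid and gamma-delta, 0.705 for cell cycle and MHC and 0.509 for NK-complex in BALB/c minus B6 in iNKT17. It was 0.214 for type 1, 0.453 for cell cycle, pro-apoptotic, oxidative phosphorylation, MHC, alpha-beta and NK/CD8, 0.342 for interferon and 0.513 for lipid in BALB/c minus B6 in ROR-. It was 0.5003 for type 1, type 2, pro-apoptotic, TCR, glycolysis, alpha-beta, neutrophil, immature thymocyte and NK/CD8, 0.715 for cell cycle, 0.588 for oxidative phosphorylation and heat-shock, 0.285 for NK-complex and B cell, 0.448 for gamma-delta and 0.416 for macrophage in iNKT17 minus gamma-delta 17.

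Leaving out each array in turn, the counts ran from 1341 (without B6 ROR- replicate 1) to 2051 (without BALB/c ROR- replicate 1) for iNKT17 minus ROR-, 742 (without BALB/c iNKT17 replicate 3) to 1150 (without B6 gamma-delta 17 replicate 1) for that difference in BALB/c, 492 (without B6 ROR- replicate 1) to 1058 (without BALB/c ROR- replicate 3) for that difference in B6, 0 (without B6 ROR- replicate 2) to 15 (without BALB/c iNKT17 replicate 2) for the interaction, 77 (without B6 iNKT17 replicate 2) to 530 (without BALB/c iNKT17 replicate 2) for BALB/c minus B6 in iNKT17, 68 (without B6 ROR- replicate 2) to 259 (without BALB/c ROR- replicate 1) for BALB/c minus B6 in ROR-, 288 (without B6 iNKT17 replicate 2) to 1115 (without BALB/c iNKT17 replicate 2) for the mean strain difference, 5 (without B6 iNKT17 replicate 2) to 63 (without B6 gamma-delta 17 replicate 1) for iNKT17 minus gamma-delta 17 and 530 (without B6 ROR- replicate 1) to 1151 (without BALB/c ROR- replicate 3) for gamma-delta 17 minus ROR-. List adjusted p-values for iNKT17 minus ROR- ran from 2.32e-06 (without BALB/c ROR- replicate 1) to 0.129 (without B6 ROR- replicate 1) for cell cycle, 0.0103 (without BALB/c iNKT17 replicate 1) to 0.0513 (without BALB/c ROR- replicate 1) for egress, 0.013 (without BALB/c ROR- replicate 2) to 0.0878 (without B6 ROR- replicate 2) for gamma-delta and 0.000314 (without BALB/c iNKT17 replicate 1) to 0.261 (without BALB/c ROR- replicate 2) for heat-shock. List adjusted p-values for BALB/c minus B6 in iNKT17 ran from 0.0178 (without B6 iNKT17 replicate 1) to 0.422 (without B6 iNKT17 replicate 2) for type 17, 0.000167 (without BALB/c iNKT17 replicate 2) to 0.123 (without B6 iNKT17 replicate 2) for lipid, 0.00701 (without B6 gamma-delta 17 replicate 1) to 0.0834 (without BALB/c iNKT17 replicate 2) for NK-complex, 0.00616 (without B6 iNKT17 replicate 2) to 0.21 (without B6 iNKT17 replicate 1) for MHC and 0.0126 (without B6 gamma-delta 17 replicate 1) to 0.128 (without B6 iNKT17 replicate 2) for gamma-delta. List adjusted p-values for BALB/c minus B6 in ROR- ran from 0.0192 (without BALB/c ROR- replicate 1) to 0.154 (without B6 ROR- replicate 2) for pro-apoptotic, 0.00349 (without B6 ROR- replicate 1) to 0.335 (without B6 ROR- replicate 2) for lipid and 0.00169 (without B6 ROR- replicate 2) to 0.144 (without B6 ROR- replicate 1) for MHC. List adjusted p-values for iNKT17 minus gamma-delta 17 ran from 2.01e-07 (without B6 gamma-delta 17 replicate 2) to 0.608 (without B6 gamma-delta 17 replicate 1) for type 1, 2.35e-06 (without B6 gamma-delta 17 replicate 1) to 0.764 (without B6 gamma-delta 17 replicate 2) for type 2, 0.000932 (without B6 iNKT17 replicate 1) to 0.997 (without B6 iNKT17 replicate 2) for cell cycle, 0.00824 (without B6 gamma-delta 17 replicate 2) to 0.317 (without B6 gamma-delta 17 replicate 1) for pro-apoptotic, 0.00967 (without BALB/c ROR- replicate 2) to 0.144 (without B6 gamma-delta 17 replicate 2) for TCR, 0.0109 (without BALB/c ROR- replicate 1) to 0.0883 (without B6 gamma-delta 17 replicate 1) for glycolysis, 0.0147 (without B6 iNKT17 replicate 1) to 0.32 (without B6 iNKT17 replicate 2) for oxidative phosphorylation, 0.000299 (without B6 gamma-delta 17 replicate 1) to 0.241 (without B6 gamma-delta 17 replicate 2) for NK-complex, 7.83e-12 (without B6 gamma-delta 17 replicate 1) to 0.462 (without B6 gamma-delta 17 replicate 2) for alpha-beta, 0.00109 (without BALB/c ROR- replicate 2) to 0.0691 (without B6 gamma-delta 17 replicate 1) for heat-shock, 0.00258 (without B6 gamma-delta 17 replicate 1) to 0.144 (without B6 gamma-delta 17 replicate 2) for B cell, 0.0322 (without B6 gamma-delta 17 replicate 2) to 0.102 (without B6 iNKT17 replicate 1) for macrophage, 2.67e-11 (without B6 gamma-delta 17 replicate 2) to 0.874 (without B6 gamma-delta 17 replicate 1) for neutrophil, 3.68e-11 (without B6 gamma-delta 17 replicate 2) to 0.141 (without B6 gamma-delta 17 replicate 1) for immature thymocyte and 8.17e-07 (without B6 gamma-delta 17 replicate 2) to 0.628 (without B6 gamma-delta 17 replicate 1) for NK/CD8.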

Other observations

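Heat-shock genes stood high on a few arrays and low on others. Hspa1b read 11.31 on BALB/c ROR- replicate 2 and 10.86 on BALB/c iNKT17 replicate 1, and 4.13 on gamma-delta 17 replicate 1. The immediate-early and heat-shock list averaged 9.02 on BALB/c ROR- replicate 2 and 6.71 and 6.87 on the gamma-delta 17 arrays.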
